A study of Pimephales promelas with 20 samples.

How the data were processed

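Gill RNA of fathead minnow (Pimephales promelas, a small freshwater fish used in toxicity testing) was measured on 20 Agilent 1-colour arrays. The groups were unexposed controls, silver nitrate (AgNO3, which releases silver ions in water) at a nominal 6 µg/L, and 20 nm silver nanoparticles (AgNP) at a nominal 200 µg/L with either a polyvinylpyrrolidone (PVP) or a citrate coating. Exposure lasted 96 h, per the labels. Each array gives the brightness of 61053 non-control spots for 49849 probes, each 60 bases long.

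The deposited scanner files hold spot intensity on a linear scale, made with Agilent Feature Extraction 10.7.3.1, per the file headers. The processed intensity had been detrended within each array, and no step between arrays is recorded, per the file headers. A deposited value table gives log2 values for the same arrays. Set against the scanner values, it is on a log2 scale and centred on each probe's middle value. The method by which its arrays were made comparable is not given in the sources used here. Its column medians ran from -0.065 to 0.041. It was used only as an alternative.

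From the processed intensities, log2 was taken and each array's 75th percentile over non-control spots was subtracted. Spots of one probe were averaged. A probe was tested if it was well above background, by the scanner software's own flag, on at least 4 arrays. This left 42883 probes, of which 22001 were well above background on all 20 arrays. No spot was saturated.

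Citrate-AgNP arrays 32 and 32-2 share a replicate number and were averaged into 1 replicate, which left 19 replicates: 5 controls, 5 AgNO3, 5 PVP-AgNP and 4 citrate-AgNP. The labels do not say that replicates are separate fish, so p-values measure the spread between these samples, which may in part be technical. All 4 groups entered one limma 3.58.1 fit (R 4.3.3, lmFit, contrasts.fit and eBayes), and each of the 6 differences between groups was tested two-sided. Adjusted p-values are Benjamini-Hochberg values within one comparison, with 0.05 as the threshold. Per-array measures were compared by exact two-sided permutation tests.

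The files give probe identifiers without gene names, and the gene table used here shares no identifier with them, so no probe was given a gene name and the gene lists and cell type markers fixed before the data were examined were not applied. Under the rule fixed for this case, at most 2 identifiers that were higher and 2 that were lower are named per comparison. Since none passed the threshold, these are the probes with the smallest p in each direction. Their 60-base sequences are given as their identity. Of the tested probes, 38299 sequences were distinct, and 4471 sequences stood under several identifiers. Fold changes against control under 2 such identifiers correlated across sequences with r = 0.876 for AgNO3, 0.879 for PVP-AgNP and 0.854 for citrate-AgNP. Probes are not independent replicates.

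The fit was tested on simulated data with the spread of the real probes. Over 42883 probes with 50 changed by each fold, an 8-fold change was called for 76% of probes in AgNO3 against control, 80% in PVP-AgNP and 68% in citrate-AgNP. A 4-fold change was called for 30%, 56% and 26%, and a 2-fold change for 4%, 6% and 0%. The simulated spread came from a fit without slide, so it includes differences between slides. Both that spread and the number of arrays limit the precision, and their shares were not tested.

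The files show 3 slides, each scanned at its own time. Slide 1 held 8 arrays, with 2 of every group. Slide 2 held 8 arrays, with 2 control, 3 AgNO3, 2 PVP-AgNP and 1 citrate-AgNP. Slide 3 held 4 arrays, with 1 control, 1 PVP-AgNP and 2 citrate-AgNP, and no AgNO3. Slide was tested as a fixed block and values are also given within slides, with array 32 left out of those so that each replicate counts on 1 slide alone, and no probe's difference given for a slide where no array of a group measured it. Other alternatives changed the background correction, the scaling, the filter on dim probes and the variance model. They also changed the treatment of arrays 32 and 32-2, the arrays used and the source of the values. Background correction by normexp (offset 50) started from the mean spot signal and the local background, not from the processed intensity. Where every array of a group left a probe below the background flag, a fold against a floor is given if most arrays of the brighter group measured it. The bright group's mean was set against that floor. Per array, the floor was the higher of the lowest signal among probes well above background and the probe's own. It is no strict limit, since an unflagged probe can have more signal than a flagged probe on the same array.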

Results

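The series asked how gill transcripts of fathead minnow differ after exposure to dissolved silver or to silver nanoparticles with a PVP or citrate coating. Gene expression was measured on 20 arrays of 4 groups, counted as 19 replicates. The 75th percentile of processed intensity ranged from 218.4 to 1015 in controls, from 516.8 to 1194 in AgNO3, from 212.9 to 1542 in PVP-AgNP and from 129.6 to 1999 in citrate-AgNP. The share of spots well above background ranged from 59.1% to 79.3% in controls, from 67.5% to 84.1% in AgNO3, from 56.1% to 85.3% in PVP-AgNP and from 52.2% to 89.0% in citrate-AgNP. Pooled over slides, no treatment's mean differed from control beyond the spread between replicates in either measure. The smallest two-sided exact permutation p over the 6 tests was 0.365, for the intensity of AgNO3, and its Benjamini-Hochberg value over the 3 treatments was 0.90. The pooled means hide opposite differences on 2 slides. On slide 1 the 6 treated arrays had 80.7% to 89.0% of spots well above background and the 2 controls 65.9% and 79.3%. On slide 2 the 6 treated arrays had 62.5% to 67.5% and the 2 controls 71.5% and 77.0%. The log2 of the 75th percentile differed from control by 1.34, 1.36 and 1.45 on slide 1 for AgNO3, PVP-AgNP and citrate-AgNP, and by -0.652, -0.639 and -0.913 on slide 2. On slide 3 it differed by -0.0369 for PVP-AgNP and -0.753 for citrate-AgNP. The change in the difference of treated from control arrays between slides 1 and 2 was tested after these values had been seen. It had an exact two-sided permutation p of 0.00128 for each measure, the smallest that 784 relabellings within slides can give. With slide as a block and labels exchanged within slides, the smallest exact permutation p of any treatment was 0.556.

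The arrays separated by slide more than by treatment. The first principal component held 21.2% of the variance of the 42883 tested probes, and 86.6% of its own variance lay between slides against 8.06% between groups. Slide 3 was the dimmest, with 75th percentiles from 129.6 to 230.4, and its repeated spots had a median coefficient of variation of 37.4% to 49.1%. On slides 1 and 2 this coefficient ranged from 7.72% to 24.6%.

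**Figure D1:**
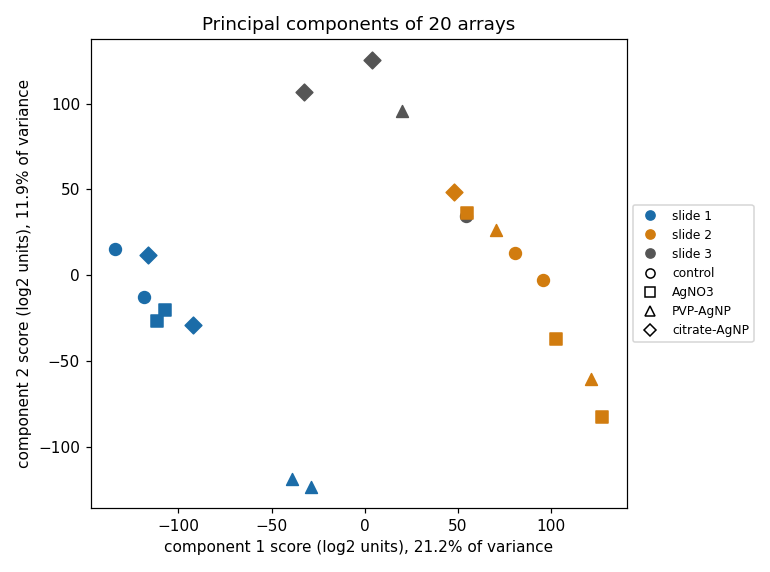
Scores of the 20 arrays on the first 2 principal components of log2 signal, with colour for the slide and marker shape for the group. Component 1 holds 21.2% of the variance and separates slide 1 from slide 2, while each group's markers are spread along it.

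AgNO3 was compared with control to find probes that differ after exposure to dissolved silver. The 2 probes with the smallest p among those higher were SINGLET_29876 and UF_Ppr_AF_109267. SINGLET_29876 (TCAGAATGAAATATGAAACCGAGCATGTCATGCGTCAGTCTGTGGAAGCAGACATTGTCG) stood at 2.07 ± 0.95 (SD, n = 5) in AgNO3 and -1.89 ± 1.2 (SD, n = 5) in controls, on the log2 scale relative to the array's 75th percentile. The difference was 3.96 (SE 0.66), a 15.6-fold higher mean, with a limma adjusted p of 0.27. UF_Ppr_AF_109267 (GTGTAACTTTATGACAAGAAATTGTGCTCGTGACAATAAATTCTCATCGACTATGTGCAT) differed by 3.07 (SE 0.67, adjusted p 0.49), and its controls were spread widely, with an SD of 2. Controls 1, 2 and 3 lay at -0.74, -0.28 and 0.57, control 5 at -3.19 and control 6 at -4.08. Control 6 did not measure the probe well above background and lies on slide 3, which holds no AgNO3 array. The means of UF_Ppr_AF_109267 in PVP-AgNP and citrate-AgNP, 1.41 and 1.24, were close to the 1.53 of AgNO3.

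The 2 lower probes were SINGLET_6226 and UF_Ppr_AF_114950. SINGLET_6226 (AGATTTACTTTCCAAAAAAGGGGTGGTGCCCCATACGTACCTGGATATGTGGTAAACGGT) stood at -1.19 ± 1.3 in AgNO3 and 1.79 ± 0.63 in controls, a difference of -2.98 (SE 0.52, adjusted p 0.27). UF_Ppr_AF_114950 (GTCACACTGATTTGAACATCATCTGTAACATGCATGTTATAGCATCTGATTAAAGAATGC) stood at 0.14 ± 0.67 in AgNO3 and 2.71 ± 0.46 in controls, a difference of -2.57 (SE 0.46, adjusted p 0.27). For all 4 probes the AgNO3 and control replicates did not overlap, which picking them by small p favours, so it is no separate support. In PVP-AgNP and citrate-AgNP, set against the same controls, UF_Ppr_AF_114950 differed by -2.46 and -1.35. SINGLET_6226 differed there by -1.76 and -1.6, and SINGLET_29876 by 1.89 and 1.57. Within slides 1 and 2, SINGLET_29876 differed by 4.8 and 3.61, UF_Ppr_AF_109267 by 2.04 and 2.84, SINGLET_6226 by -2.43 and -3.1, and UF_Ppr_AF_114950 by -2.66 and -2.76. With normexp background correction the differences in that order were 3.44, 2.20, -2.71 and -2.41. With slide as a block the adjusted p was 0.19 for SINGLET_29876 and 0.28 for the other 3, and with repeated arrays also as a random block 0.14 and 0.33. Averaging PVP-AgNP arrays 24 and 25, which may be 1 fish, changes the shared estimate of the spread. The limma adjusted p was then 0.54 for UF_Ppr_AF_109267 and 0.40 for the other 3.

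No probe passed the adjusted threshold for AgNO3 against control by limma. At an unadjusted p under 0.05 there were 2608 probes, 818 higher and 1790 lower (1150 and 1445 with quantile normalization), where 2144 are expected by chance. An unmoderated test of each probe gave 2424 at the unadjusted threshold and 1 after adjustment. The replicates of both groups did not overlap at 450 probes, where chance gives 340 (0.794% of those tested). The 95% interval excluded a 4-fold change for 82.7% of probes and a 2-fold change for 28.5%. With normexp background correction 1 probe passed, SINGLET_29876, at an adjusted p of 0.014, and 1221 lay under the unadjusted threshold. Over the 22001 probes well above background everywhere, 1678 did.

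PVP-AgNP was compared with control to find probes that differ after exposure to PVP-coated particles. The higher probes were UF_Ppr_AF_103210 and CONTIG9825. UF_Ppr_AF_103210 (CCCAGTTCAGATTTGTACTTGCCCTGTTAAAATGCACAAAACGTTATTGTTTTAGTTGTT) stood at 1.33 ± 0.48 (SD, n = 5) in PVP-AgNP and -0.37 ± 0.46 (SD, n = 5) in controls, a difference of 1.70 (SE 0.3) or 3.25-fold, with a limma adjusted p of 0.16. CONTIG9825 (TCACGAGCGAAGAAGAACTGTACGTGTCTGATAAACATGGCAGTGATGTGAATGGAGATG) differed by 3.25 (SE 0.59, adjusted p 0.16). It was well above background on 5 of 5 PVP-AgNP arrays and on 1 of 5 control arrays, and with normexp the difference of CONTIG9825 was 0.69 and that of UF_Ppr_AF_103210 was 0.98. Within slides 1, 2 and 3, UF_Ppr_AF_103210 differed by 1.88, 1.73 and 1.27. CONTIG9825 differed by 3.77 within slide 2, where 1 of 2 controls measured it, and no control on slides 1 and 3 did.

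The lower probes were UF_Ppr_AF_115037 and CONTIG10295. UF_Ppr_AF_115037 (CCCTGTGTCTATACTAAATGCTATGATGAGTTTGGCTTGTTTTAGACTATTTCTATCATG) stood at 0.43 ± 0.076 in PVP-AgNP and 1.63 ± 0.34 in controls, a difference of -1.19 (SE 0.21, adjusted p 0.16). Its differences within the slides were -1.18, -1.22 and -1.16, and with normexp it differed by -1.1. CONTIG10295 (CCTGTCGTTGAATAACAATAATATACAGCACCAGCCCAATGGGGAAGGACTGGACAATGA) differed by -2.5 (SE 0.46, adjusted p 0.16), by -2.1 and -2.48 within slides 1 and 2, and by -1.38 with normexp. It was not well above background on the PVP-AgNP array of slide 3. With slide as a block the adjusted p of each of the 4 probes was 0.076, and with repeated arrays (24 and 25, 32 and 32-2) also as a random block it was 0.16. PVP-AgNP and control replicates did not overlap at any of the 4, which picking them by small p favours, so it is no separate support. In AgNO3 and citrate-AgNP, UF_Ppr_AF_115037 differed from the same controls by -0.91 and -0.77, and UF_Ppr_AF_103210 by 0.75 and 0.43. CONTIG9825 differed there by 0.35 and 0.21, and CONTIG10295 by 0.047 and -0.65.

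No probe passed the adjusted threshold for PVP-AgNP against control by limma. At an unadjusted p under 0.05 there were 3503 probes, 1722 higher and 1781 lower, against 2144 expected by chance. The split was 1217 higher and 2247 lower with median scaling, and 552 and 1052 with normexp. An unmoderated test of each probe gave 3059 at the unadjusted threshold and 1 after adjustment. If all 5 PVP-AgNP replicates are separate fish, the replicates did not overlap at 614 probes, 1.43% against 0.794% by chance. On the same condition the 95% interval excluded a 4-fold change for 81.2%. PVP-AgNP replicates 24 and 25 were in the same state at 100% of 246 probes that are high on some arrays and low on others, against at most 69.5% for other pairs apart from citrate-AgNP 32 and 32-2 (74.6% with probes that follow the slide kept). With these 2 arrays averaged, which leaves 4 PVP-AgNP replicates, no probe passed, 2969 lay under the unadjusted threshold, and the 4 named probes each had an adjusted p of 0.29. The replicates then did not overlap at 868 probes, 2.02% against 1.59% by chance. Normexp gave 1604, the filter to probes above background everywhere gave 2159, and quantile normalization let 1 probe pass.

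**Figure D2:**
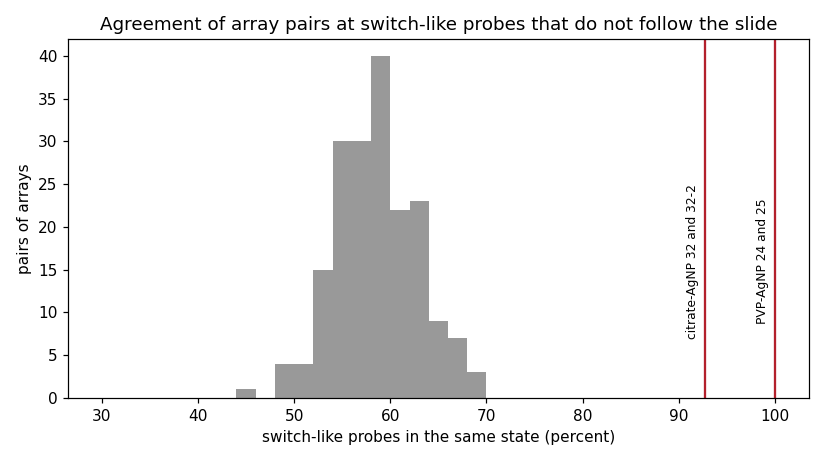
Histogram of the percent of 246 switch-like probes (high on some arrays and low on others, not following the slide) at which 2 arrays are in the same state, over 188 pairs of arrays in grey. Red lines mark PVP-AgNP 24 and 25 at 100% and citrate-AgNP 32 and 32-2 at 92.7%, against at most 69.5% for the other pairs, or 100%, 77.6% and at most 74.6% with 49 probes that follow the slide kept.

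**Figure D3:**
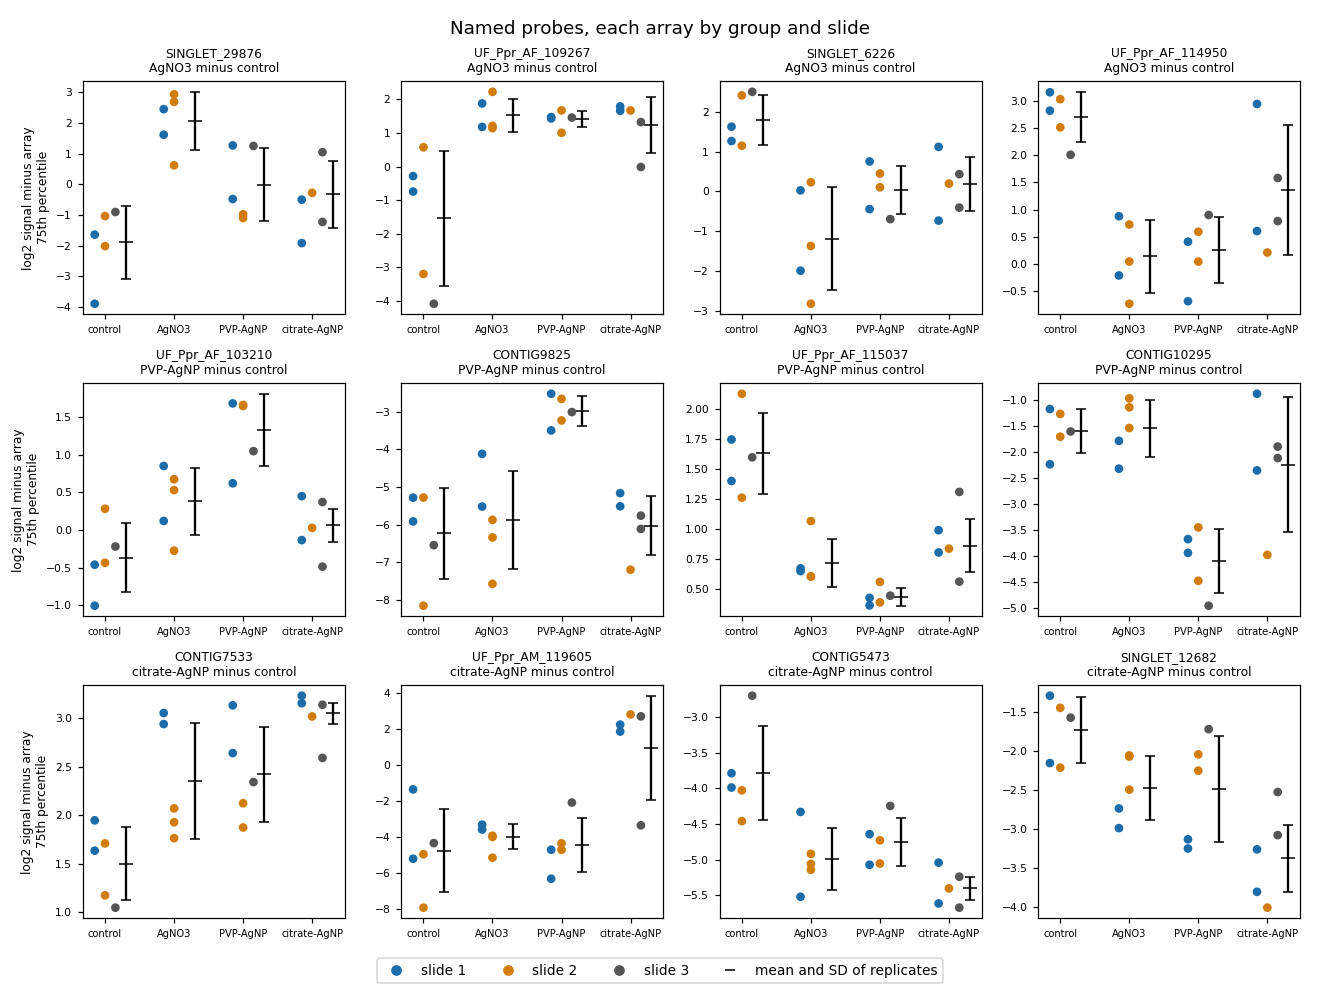
Log2 signal relative to each array's 75th percentile for the 12 probes named against control, with 1 point per array, colour for the slide, and the mean and SD of the replicates beside each group. UF_Ppr_AF_115037 stands at 0.43 in PVP-AgNP and 1.63 in controls on average, and no probe shown passed the adjusted threshold.

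Citrate-AgNP was compared with control in the same way for citrate-coated particles. The higher probes were CONTIG7533 and UF_Ppr_AM_119605. CONTIG7533 (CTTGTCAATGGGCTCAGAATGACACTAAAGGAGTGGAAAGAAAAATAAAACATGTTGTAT) stood at 3.05 ± 0.11 (SD, n = 4) in citrate-AgNP and 1.5 ± 0.38 (SD, n = 5) in controls, a difference of 1.55 (SE 0.33) with a limma adjusted p of 1. With slide as a block its adjusted p was 0.083, and with repeated arrays also as a random block it was 0.14, the smallest of any probe in this comparison. UF_Ppr_AM_119605 (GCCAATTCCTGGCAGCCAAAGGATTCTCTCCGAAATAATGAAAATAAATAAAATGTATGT) differed by 5.70 (SE 1.2, adjusted p 1), with overlapping groups, since replicate 36 lay at -3.35 and the other citrate-AgNP replicates between 1.86 and 2.81.

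The lower probes were CONTIG5473 and SINGLET_12682. CONTIG5473 (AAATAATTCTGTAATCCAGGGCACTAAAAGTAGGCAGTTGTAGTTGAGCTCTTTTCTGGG) differed by -1.61 (SE 0.33, adjusted p 1), was well above background on 2 of 5 citrate-AgNP arrays, and differed by -0.30 with normexp. SINGLET_12682 (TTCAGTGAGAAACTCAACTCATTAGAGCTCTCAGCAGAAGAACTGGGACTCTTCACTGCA) stood at -3.37 ± 0.43 in citrate-AgNP and -1.73 ± 0.42 in controls, a difference of -1.64 (SE 0.35, adjusted p 1), or -0.86 with normexp. With normexp CONTIG7533 differed by 1.44 and UF_Ppr_AM_119605 by 4.03. Within slides 1, 2 and 3, CONTIG7533 differed by 1.4, 1.58 and 2.09, UF_Ppr_AM_119605 by 5.33, 9.24 and 0.99, and SINGLET_12682 by -1.81, -2.17 and -1.5. On slide 2, 1 of 2 controls measured UF_Ppr_AM_119605. CONTIG5473 differed by -1.44 within slide 1 and was not well above background in citrate-AgNP on slides 2 and 3. In AgNO3 and PVP-AgNP, CONTIG7533 differed from the same controls by 0.85 and 0.92, and UF_Ppr_AM_119605 by 0.76 and 0.32. CONTIG5473 differed there by -1.2 and -0.96, and SINGLET_12682 by -0.73 and -0.74. No probe passed the adjusted threshold by limma. There were 1868 probes at an unadjusted p under 0.05, 953 higher and 915 lower (940 and 1322 with quantile normalization), below the 2144 expected by chance. Other splits of the same replicates had a median count of 1718. An unmoderated test gave 2127 and none after adjustment. The replicates did not overlap at 736 probes, 1.72% against 1.59% by chance, and the 95% interval excluded a 4-fold change for 80.4%. With slide as a block 3491 lay under the unadjusted threshold and none passed, with arrays 32 and 32-2 counted separately. It was 2951 without array 32 and 2513 with repeated arrays also as a random block. Normexp gave 700 and the filter to probes above background everywhere gave 1207.

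The coatings were compared at their shared nominal dose of 200 µg/L. UF_Ppr_AF_113317 (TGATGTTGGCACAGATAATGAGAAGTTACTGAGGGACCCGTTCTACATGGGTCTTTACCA) was higher in PVP-AgNP than in citrate-AgNP by 2.20 (SE 0.45, limma adjusted p 0.63), and CONTIG9825 by 3.04 (SE 0.62, adjusted p 0.63). Both were well above background on 5 of 5 PVP-AgNP arrays and 2 of 5 citrate-AgNP arrays, and with normexp they differed by 0.55 and 0.61. SINGLET_32405 (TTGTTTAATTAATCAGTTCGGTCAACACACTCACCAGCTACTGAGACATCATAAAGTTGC) differed by -2.40 (SE 0.37, adjusted p 0.15), and by -1.11 with normexp. SINGLET_10619 (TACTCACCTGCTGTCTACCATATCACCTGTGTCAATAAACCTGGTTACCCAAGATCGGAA) differed by -1.64 (SE 0.33, adjusted p 0.63), and by -1.23 with normexp. Within slides 1, 2 and 3, SINGLET_10619 differed by -1.15, -2.26 and -1.76. Within slides 1 and 2, UF_Ppr_AF_113317 differed by 3.15, with 1 of 2 citrate-AgNP arrays measuring it, and 1.83, and SINGLET_32405 by -1.83 and -2.79. CONTIG9825 differed by 2.33 within slide 1. On the slides left out, no array of a group measured the probe. No probe passed, 3334 lay at an unadjusted p under 0.05 (1865 higher and 1469 lower in PVP-AgNP) against 2144 by chance, and an unmoderated test gave 4055 and none after adjustment. The larger side changed with processing, to 1237 higher and 2021 lower with median scaling and 362 and 701 with normexp. The replicates did not overlap at 1558 probes, 3.63% against 1.59% by chance if 24 and 25 are separate fish. With 24 and 25 averaged they did not overlap at 2300 probes, 5.36% against 2.86% by chance, 2685 lay under the unadjusted threshold, none passed, and the smallest adjusted p was 0.49, for SINGLET_32405. With 24 and 25 counted as separate fish, the 95% interval excluded a 4-fold difference between coatings for 76.2% of probes and a 2-fold difference for 23%. Single arrays moved the count: it was 1778 without PVP-AgNP replicate 24 and 5236 without replicate 26. Array weights gave 5699, normexp 1063, the filter to probes above background everywhere 1734, and the fit of these 2 groups alone let 1 probe pass, or none with 24 and 25 averaged.

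PVP-AgNP and AgNO3 differ in nominal dose, 200 against 6 µg/L, as well as in the form of silver. UF_Ppr_AF_113317 was higher in PVP-AgNP by 2.56 (SE 0.42, limma adjusted p 0.39). SINGLET_45032 (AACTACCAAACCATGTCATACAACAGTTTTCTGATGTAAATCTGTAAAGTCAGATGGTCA) was not well above background on any AgNO3 array and was higher in PVP-AgNP, where 4 of 5 arrays measured it (adjusted p 0.62). Its PVP-AgNP mean was 11.3-fold above the floor used for AgNO3. That fold rests on the processed signal and counts 24 and 25 as 2 fish. With them averaged it was 8.17-fold (adjusted p 1). With normexp SINGLET_45032 differed by 1.40 on the log2 scale, less than either fold, so neither is a lower bound. UF_Ppr_AF_113317 differed by 0.99 with normexp. SINGLET_45032 stood at -4.54 in controls, -3.54 in PVP-AgNP, -4.51 in citrate-AgNP and -7.96 in AgNO3. PVP-AgNP differed from control by 1.00 (SE 0.84), so the gap lay mostly in low AgNO3 values. CONTIG10295 differed by -2.55 (SE 0.46, adjusted p 0.58), and by -1.30 with normexp. UF_Ppr_AF_100045 (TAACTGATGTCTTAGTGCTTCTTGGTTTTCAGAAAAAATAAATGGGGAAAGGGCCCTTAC) differed by -7.04 (SE 1.4, adjusted p 0.62), was well above background on 1 of 5 PVP-AgNP arrays, and differed by -3.57 with normexp. Within slides 1 and 2, UF_Ppr_AF_113317 differed by 1.97 and 3.46, CONTIG10295 by -1.75 and -2.75, and UF_Ppr_AF_100045 by -7.53 within slide 1, where 1 of 2 PVP-AgNP arrays measured it, and none on slide 2 did. No probe passed, and 1595 lay at an unadjusted p under 0.05 (1015 higher and 580 lower, but 553 and 932 with median scaling and 627 and 848 with quantile normalization) against 2144 by chance, with 1669 by an unmoderated test and none after adjustment. The replicates did not overlap at 285 probes, 0.665% against 0.794% by chance, and with 24 and 25 averaged at 425, 0.991% against 1.59%. In the fit of these 2 groups alone 3 probes passed, among them UF_Ppr_AF_100045 at 0.010. That fit leaves out the spread of this probe in controls (SD 3.3) and citrate-AgNP (SD 3.2). Its control values alone ran from -6.73 to 1.18. With 24 and 25 averaged, 3 passed in the fit of these 2 groups, UF_Ppr_AF_100045 at 0.030, and none in the fit of all groups, where its adjusted p was 1 and the smallest of any probe was 0.95. The unadjusted count was 1049 without PVP-AgNP replicate 24, 3134 with array weights, 2416 with slide as a block, 1629 with repeated arrays also as a random block, 793 with normexp and 771 over probes above background everywhere.

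Citrate-AgNP and AgNO3 were compared with the same difference in dose. CONTIG9337 (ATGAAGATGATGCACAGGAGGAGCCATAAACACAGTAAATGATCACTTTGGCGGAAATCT) was not well above background on any AgNO3 array and was on 2 of 5 citrate-AgNP arrays, so no fold is given. It was higher in citrate-AgNP with a limma adjusted p of 0.11, or 0.77 with normexp. SINGLET_40122 (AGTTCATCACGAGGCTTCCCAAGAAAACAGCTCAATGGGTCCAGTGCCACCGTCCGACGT) differed by 2.00 (SE 0.38, adjusted p 0.59), and by 1.1 with normexp. CONTIG3030 (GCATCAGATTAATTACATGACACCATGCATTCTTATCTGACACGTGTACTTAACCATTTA) differed by -2.82 (SE 0.59, adjusted p 0.59), and CONTIG3796 (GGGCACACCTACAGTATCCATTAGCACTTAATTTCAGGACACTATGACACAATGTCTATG) by -8.04 (SE 1.7, adjusted p 0.59). Their sizes are uncertain, since CONTIG3030 was well above background on 2 of 5 citrate-AgNP arrays and CONTIG3796 on 1 of 5, and with normexp they differed by -0.68 and -4.71. Within slides 1 and 2, SINGLET_40122 differed by 1.11 and 2.86. CONTIG3030 differed by -2.16 within slide 1 and CONTIG3796 by -8.75, with 1 of 2 citrate-AgNP arrays measuring it, and the citrate-AgNP array of slide 2 measured neither. No probe passed, and 1666 lay at an unadjusted p under 0.05 (1222 higher and 444 lower, but 704 and 925 with quantile normalization) against 2144 by chance, with 1765 by an unmoderated test and none after adjustment. The replicates did not overlap at 594 probes, 1.39% against 1.59% by chance. Without array 32-2 CONTIG9337 passed alone, at a limma adjusted p of 0.026. In the fit of these 2 groups 2 probes passed, among them CONTIG3796 at 0.011. That fit leaves out the spread of CONTIG3796 in controls (SD 4) and PVP-AgNP (SD 3.2). The unadjusted count was 1038 without citrate-AgNP replicate 36, 726 with normexp and 679 over probes above background everywhere.

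**Figure D4:**
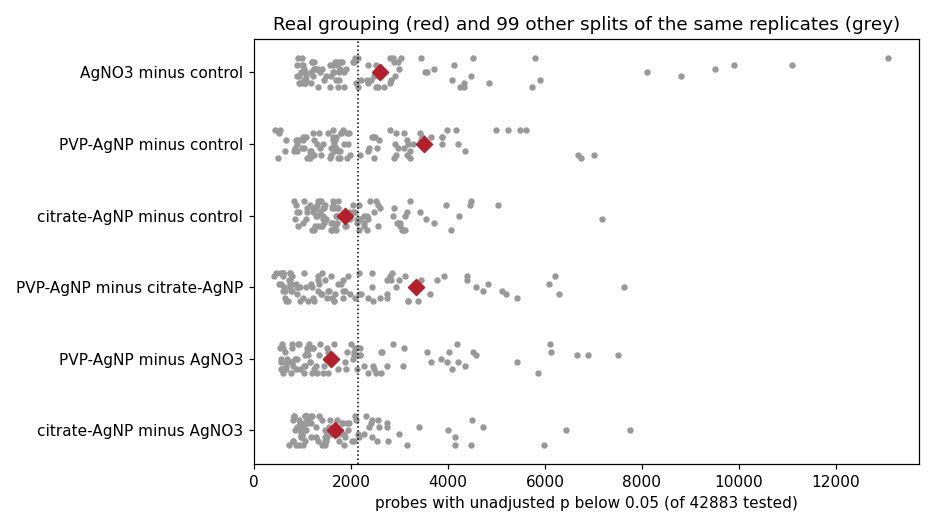
Number of probes at an unadjusted p under 0.05 for each comparison, with the real grouping in red, other splits of the same replicates in grey, and the 2144 expected by chance as a dotted line. The real counts, from 1595 to 3503, lie inside the range of the other splits in every comparison. PVP-AgNP 24 and 25 count as separate replicates in the splits.

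The 3 treatments share their controls, so their fold changes correlate by construction. Across probes, which are not independent replicates, fold changes of AgNO3 and PVP-AgNP had r = 0.597, those of AgNO3 and citrate-AgNP 0.477, and those of PVP-AgNP and citrate-AgNP 0.388. In 100 simulated groupings with no effect the mean r was 0.493, 0.478 and 0.464. The observed covariances were 0.223, 0.16 and 0.143, against simulated means of 0.19, 0.197 and 0.189, and all lay within the central 95% of the simulated values (0.04 to 0.44, 0.0542 to 0.451 and 0.04 to 0.403). With controls split so that each treatment was set against other control arrays, the mean r over splits was 0.08, -0.03 and -0.06. The parts can hold controls of unlike slides, which can lower r, and no value without effect was simulated for them. These r therefore do not decide whether the treatments share a response.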

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

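The tests of the pair 24 and 25, of array 32 against 32-2, of the splits and of the repeat between slides were chosen after the results they bear on had been seen, as was setting aside probes that follow the slide. Tests of bright probes and of RNA integrity were chosen before their results.

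Each group was searched for a sample far from the rest in 6 array measures and in the named probes. Chance gives such a sample in about 1 of 20 groups, and 2 of 24 groups of array measures and 7 of 84 groups of probe values held one. Control 6 had 3267 non-uniform spots where the other controls had 4 to 14, and PVP-AgNP 26 had 1781 where the others had 2 to 128. Both lie on slide 3, whose 4 arrays all had 680 to 3267 such spots, against 2 to 26 on slide 1 and 6 to 128 on slide 2. The high counts thus go with the slide and not with these 2 samples alone. Among probe values, citrate-AgNP 36 stood at -0.012 for UF_Ppr_AF_109267 and at -3.35 for UF_Ppr_AM_119605, and citrate-AgNP 34 at -7.19 for CONTIG9825. AgNO3 17 stood at 1.06 for UF_Ppr_AF_115037, and AgNO3 13 at -8.76 for SINGLET_45032. For CONTIG3796, control 6 stood at -6.17 where the other controls lay between 2.53 and 3.01, and PVP-AgNP 21 at -4.99.

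The arrays separated by slide. Citrate-AgNP 32 and 32-2 lie on slides 3 and 1. Their difference followed the difference between those slides over the other arrays across probes with r = 0.633. If they are 1 sample, as the labels' shared number allows, this argues against differences between samples alone for slides 1 and 3. A slide, scan or processing batch stays a candidate there. The first component mainly separates slide 1 from slide 2. No arrays with a shared number link those 2 slides, so for them this test decides nothing. Of the 49 switch-like probes that were high on slide 1 arrays alone, 48 were low on array 32 and 49 were high on array 32-2. Dimness is argued against as the whole cause, since 96.9% of the first component's variance lay between slides over the brightest 25% of probes. RNA integrity stays open, because 32.4% of the variance of an index of coding-like against 3' end-like probes lay between slides.

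PVP-AgNP replicates 24 and 25 were in the same state at 100% of 246 switch-like probes, which were picked on 16 other arrays by a gap of over 2.5 on the log2 scale. The highest share among other pairs on one slide was 69.5%, and among other PVP-AgNP pairs 64.2%, so neither a shared slide nor the treatment accounts for it. Citrate-AgNP 32 and 32-2 reached 92.7%. With the 49 probes that follow the slide kept, 24 and 25 stayed at 100%, while 32 and 32-2 reached 77.6% and the highest other pair 74.6%. The values suggest that 24 and 25 may be 1 fish, or 1 RNA, on 2 arrays, which the labels do not say. They were not copies, since 2356 of 22001 bright probes differed over 2-fold between them.

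In the deposited value table, the columns of citrate-AgNP 32 and 32-2 followed each other's scanner signal. The lower of the 2 crossed correlations across probes was 0.989, while their own were 0.403 and 0.394. Another normalization does not account for it, since the lowest correlation over the other 18 columns was 0.952. An exchange of the 2 columns is a candidate explanation, and no biological one was tested. The comparisons average both scanner arrays and do not use these columns. Values without array 32-2 or without array 32 rest on the names of the scanner files.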

How the results depend on the processing

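The averaging of 24 and 25 (also in the fit of 2 groups), the random block for the pairs 24 and 25, and 32 and 32-2, the removal of slide 3, the averaging of one sequence, slide as a block for the array measures and the removal of both arrays of citrate-AgNP 32 were chosen after the data were seen. No paired analysis was possible because the groups share no replicate number. The gene list tests and the median over probes of a gene were not run, since probes carry no gene names. In the order AgNO3, PVP-AgNP and citrate-AgNP against control, PVP-AgNP against citrate-AgNP, PVP-AgNP against AgNO3 and citrate-AgNP against AgNO3, 0 probes passed at an adjusted p under 0.05, and 2608, 3503, 1868, 3334, 1595 and 1666 lay at an unadjusted p under 0.05. Normexp let 1 probe pass for AgNO3, and quantile normalization 1 for PVP-AgNP. The fit of the 2 groups compared let 1, 3 and 2 pass in the last 3 comparisons, and with 24 and 25 averaged 3 for PVP-AgNP against AgNO3 and 0 for the other PVP-AgNP comparisons. A plain test of each probe at an unadjusted 0.05 gave 2424, 3059, 2127, 4055, 1669 and 1765. Unadjusted counts with normexp were 1221, 1604, 700, 1063, 793 and 726, and over probes well above background on all arrays, where fewer were tested, 1678, 2159, 1207, 1734, 771 and 679. Array weights gave 5699 for PVP-AgNP against citrate-AgNP and 3134 for PVP-AgNP against AgNO3. Slide as a block gave 3491 for citrate-AgNP and 2416 for PVP-AgNP against AgNO3. Except where construction shows it, the cause was not tested. Leaving out single arrays gave 0 adjusted calls everywhere, except 1 for citrate-AgNP against AgNO3 without array 32-2. The unadjusted counts then ran from 2176 to 3255, 2529 to 4678, 1481 to 2454, 1778 to 5236, 1049 to 2293 and 1038 to 2271. The share of higher calls depended on scaling: for AgNO3 it was 31.4% and 44% with quantile normalization, for PVP-AgNP 49.2% and 35% with median scaling, for PVP-AgNP against citrate-AgNP 55.9% and 38% with median scaling, for PVP-AgNP against AgNO3 63.6% and 37% with median scaling, and for citrate-AgNP against AgNO3 73.3% and 43% with quantile normalization.

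The correlations of AgNO3 and PVP-AgNP, AgNO3 and citrate-AgNP, and PVP-AgNP and citrate-AgNP fell with split controls to 0.077, -0.033 and -0.059. Splitting takes out the shared controls, but it can also set controls of unlike slides against each other. These 2 causes of the fall were not told apart. Over probes above background everywhere the first 2 correlations were 0.64 and 0.57. Without single arrays they ran from 0.52 to 0.67, 0.38 to 0.57 and 0.29 to 0.47. The total signal difference of citrate-AgNP from control, -0.0995, was 0.0044 with the median raw signal and 0.213 with slide as a block and array 32 left out, where its difference in percent of detected spots, -2.24, was 0.579. Without single arrays, total signal differences on the log2 scale ran from 0.226 to 0.78 for AgNO3, -0.052 to 0.66 for PVP-AgNP and -0.794 to 0.52 for citrate-AgNP, and differences in percent of detected spots from 0.59 to 5.64, -2.73 to 4.55 and -9.14 to 3.12. No named probe changed direction under any alternative that measured it, but sizes depended on the background correction. The probes were picked for their small p in these same data, so a kept direction is no separate support. Normexp made all 22 differences of named probes measured in both groups smaller, to 18.7% to 93.9% of their size. Its added offset shrinks differences between dim signals, but it also starts from another signal than the processed intensity. UF_Ppr_AF_103210, well above background on 5 of 5 PVP-AgNP and 5 of 5 control arrays, fell from 1.70 to 0.98 against control. Which of these changes shrank the differences was not tested. CONTIG9825 fell from 3.25 to 0.69 against control and UF_Ppr_AF_113317 from 2.20 to 0.55 against citrate-AgNP. CONTIG5473 went from -1.61 to -0.30 and CONTIG3030 from -2.82 to -0.68. Of 42883 tested probes, 22001 were well above background on all arrays, so differences at the others rest in part on arrays that did not measure them. Without slide 3, the dimmest, 0 probes passed in all 6 comparisons and unadjusted counts were 2577, 5132, 1582, 4011, 2145 and 1163.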

Other observations

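The splits and relabellings were chosen after the counts had been seen, and the protein signature tests before. The real count of adjusted calls was 0 in each comparison, which all 100 splits of the replicates reach by construction, so this count cannot test chance. The highest other counts were 5522 for AgNO3, 3 for PVP-AgNP and 4 for citrate-AgNP against control, 3 for PVP-AgNP against citrate-AgNP, 382 for PVP-AgNP against AgNO3 and 63 for citrate-AgNP against AgNO3. For unadjusted counts, these splits, which ignore slide, could not exclude chance in any comparison. In that order 32, 16, 48, 18, 48 and 44 splits gave a count as large as the real 2608, 3503, 1868, 3334, 1595 and 1666. The highest others were 13068, 7003, 7173, 7625, 7499 and 7758. The medians of the others were 1852, 1795, 1718, 1592, 1530 and 1485. Each real count lies above its median, also where it lies under the 2144 expected by chance. In the comparisons with PVP-AgNP, replicates 24 and 25, which may be 1 fish, counted as separate replicates. The real grouping keeps them together and a split can part them, so those numbers hold only if 24 and 25 are separate fish. The split with 13068 set 4 slide 1 arrays and 1 of slide 2 against 4 of slide 2 and 1 of slide 3, so the slides are a structure larger than any treatment here.

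With slide as a block, array 32 left out and labels exchanged only within slides, 3 of 60 relabellings gave as many unadjusted probes as the real 3506 of AgNO3 (highest other 3837). The numbers were 6 of 36 for the 5161 of PVP-AgNP (highest other 9064), 8 of 36 for the 2951 of citrate-AgNP (4349) and 3 of 36 for the 4256 of PVP-AgNP against citrate-AgNP (6630). Chance was not excluded in these 4 comparisons. In the comparisons with PVP-AgNP, replicates 24 and 25 counted as separate replicates here too. The real grouping keeps them together and a relabelling can part them, so those numbers hold only if 24 and 25 are separate fish.

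A hypothesis that a treatment effect repeats between slides was tested on fold changes from slide 1 against those from slide 2 over 22001 bright probes. For AgNO3 r was 0.181, and a share of 0.0333 of 60 relabellings within slides gave r as large, which is consistent with a small AgNO3 effect on both slides. The highest other r was 0.194, and the p was not corrected over the 3 treatments tested. For PVP-AgNP r was 0.114 (share 0.167 of 36, with 24 and 25 counted as separate replicates) and for citrate-AgNP -0.013 (share 0.556 of 18). The smallest share these 2 designs can give is 0.0556, so neither could fall under 0.05 as AgNO3 could (smallest 0.0167), and they decide nothing.

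Probes whose 60 bases encode a protein signature in a sense frame were tested as sets with camera and a preset correlation of 0.01. The smallest adjusted p over the 3 treatments was 0.006 for 46 zinc finger linker probes, 0.019 for 10 protein kinase active site probes, 0.026 for 14 collagen repeat probes and 0.66 for 6 RNA recognition motif probes. The zinc finger probes had a median difference from control of 0.24 in PVP-AgNP, with 38 of 46 higher, and -0.17 in citrate-AgNP, with 14 of 46 higher. The kinase probes had a median of 0.32 in PVP-AgNP, with 10 of 10 higher, and the collagen probes 0.65 in citrate-AgNP, with 13 of 14 higher. None of these calls held with an estimated correlation: adjusted p = 0.64 for zinc finger and 0.28 for kinase probes in PVP-AgNP, and 0.69 for zinc finger and collagen probes in citrate-AgNP. Whether these sets move with treatment stays open.

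An index of RNA integrity was the median centred signal of coding-like bright probes minus that of 3' end-like ones. End-like probes held AATAAA or ATTAAA (3951 probes). Coding-like probes held neither and had a reading frame without stop codon (15192 of 22001 bright probes). This loose rule can also admit sequence that is not coding, and the index was not checked against measured RNA integrity. Pooled over slides, the index gave a smallest exact permutation p of 0.468 against control over the 3 treatments. This decides nothing, because the difference of treated from control arrays was 0.288 on slide 1 and -0.0893 on slide 2, a change with an exact permutation p of 0.0102 over 784 relabellings within slides, tested after the index had been seen. Array intensity changed between these slides with the same signs, 1.38 and -0.691 on the log2 scale, and the index was not separated from it. The smallest exact permutation p of any treatment for the index was 0.417 with slide as a block and array 32 left out.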
